A study of Homo sapiens with 8 samples.

How the data were processed

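The data are 8 Illumina bead arrays (48802 probes each) hybridised with biotin-labelled RNA from 4 human embryonic stem cell lines, 2 arrays per line. The lines are parental H9, an established embryonic stem cell line, the control clone 3, and the ZFX clones 2 and 5. Per the labels' protocols, a bacterial artificial chromosome (BAC) holding the ZFX locus was put into the cells, clones were picked by drug resistance, and higher ZFX was checked by qRT-PCR. Groups and replicate numbers were taken from the sample titles.

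The authors deposited a table of probe intensity on a linear scale, with a detection p-value for each probe, and a separate table of processed values. BeadStudio was used, per the submitters' processing notes, with its version and the remaining steps not given in the sources used here. In the deposited intensity table the medians differ between arrays, from 60.4 to 67.8, so these values were treated as not normalized. The deposited detection p-value moves in steps of 1 in 759, which is the number of negative control probes it implies. The authors' processed values are on a log2 scale, judged by their slope of 0.980 to 1.05 on the log2 intensity of bright probes. All 8 columns share the same median of 6.76, and each column ranked its probes like its own array (rank correlation 0.99975, at most 0.879 with any other array). How the authors' values were corrected for background is unknown, so they served only as an alternative.

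Intensities were corrected for background by the normexp method of limma 3.58.1 in R 4.3.3, with an offset of 16 and the negative controls inferred from the detection p-values. They were then quantile normalized between arrays and put on the log2 scale. Probes with a detection p under 0.05 on at least 2 arrays were kept, which left 23280. Gene names came from the platform annotation, which gave 1 symbol to 28098 probes, several to 13 and none to 20691. Of these probes, 28059 were matched by Entrez ID to the reference gene table (GRCh38.p14), and no symbol differed. That table served for names, chromosomes and neighbour order only, because the files name no genome build. For each gene the probe with the highest mean was tested, and unnamed probes were tested singly. This gave 19124 tests, 12590 of them of named genes, which are all called genes below. For 3242 genes over 1 probe was kept, and for named genes a probe that did not pass where the tested one did is given at the comparison. A gene with no probe detected on any array of a group has only a bound there. Its fold is then given as "at least", from the bright group's mean and the higher of the dim value and the dimmest detected probe of each array.

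The ZFX lines were compared with the control lines by limma, with the line as a random block, since 2 arrays of a line are not independent samples of the condition. The estimated correlation of arrays of a line was 0.353. Pairs of lines were compared in a model with 4 line means, whose p-values measure the spread within lines. Both fits used moderated variances with an intensity trend and Benjamini-Hochberg adjustment, called at 0.05. Gene lists were tested with cameraPR at a preset correlation of 0.01, adjusted over the 34 lists, and again with a correlation estimated from the residuals. The lists cover developmental lineages, pluripotency, signalling targets, stress responses, chromosome segments and the ZFX locus, with 451 of their 619 genes tested.

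Designs, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took ZFX, then the 12 largest rises and 12 largest falls among called genes with the same sign in all 4 pairs of a ZFX and a control line. It also took the 8 largest changes each way between the 2 control lines and between the 2 ZFX lines, and up to 4 members of each list. Unnamed loci, XIST and Y-linked genes were left out of it. Where 5 or fewer members of a list passed, members beyond these were named after their values were seen.

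The fits were tested on simulated arrays with the real means, within-line spreads shrunk toward their median, and the 1 estimated line correlation. Line effects were drawn independently for each gene, so differences between lines as wide as those of clone 3 were not imitated. Over 5 simulations of the comparison of ZFX and control lines on 19124 genes, of which 200 were changed, changes of 0.5 on the log2 scale were called in 49.2% of genes and changes of 1 in 98.8%. Changes of 1.5 and 2 were called in 100% of genes. False calls made up 8.89% of the calls on average, above the nominal 5%, and simulations without any change called 0 to 2 genes. In the same 5 simulations, a list of 9 genes shifted by 1 log2 unit had an unadjusted cameraPR p under 0.05 in 5 runs and an unshifted list in 0. Genes were simulated without correlation between them, so the rate of false calls among real lists was not measured. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Alternatives varied the background correction, normalization, filter, probe rule, model of the line, variance trend, array weights, controls, replicates and list test.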

Results

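Gene expression was profiled in H9 human embryonic stem cells and in clones made from them, to ask how cells with extra ZFX, an X-linked zinc finger transcription factor, differ from cells without it. The 2 ZFX lines were clones 2 and 5. The 2 control lines were the parental H9 and clone 3, a wild-type clone. The labels do not say whether clone 3 went through drug selection like the ZFX clones, so comparisons with clone 3, and those of ZFX with control lines, do not separate selection from the other differences between lines. Each line was measured on 2 arrays, so the number of arrays limits the precision. Nothing in the labels says that the arrays of a line came from separate cultures, so the spread within a line may be technical. P-values of line pairs measure only that spread. Those of ZFX against control lines also take in spread between lines, through 1 correlation shared by all genes. List p-values from cameraPR set the listed genes against the other genes and do not measure spread between arrays or lines. Between 19177 and 20588 probes were detected per array, at a signal over background of 12.3 to 15.7. Across genes, arrays of a line correlated at 0.994. Clone 3 stood apart from the other lines, at 0.981 to 0.985, and the first principal component (42.4% of the variance) separated it from them.

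ZFX itself was higher in both ZFX lines than in both controls. Its mean log2 intensity was 6.02 ± 0.0509 (SD, n = 2) in H9, 6.19 ± 0.0943 (SD, n = 2) in clone 3, 7.60 ± 0.0681 (SD, n = 2) in clone 2 and 7.30 ± 0.318 (SD, n = 2) in clone 5. The log2 fold of ZFX lines over control lines was 1.34 (SE 0.163, limma adjusted p = 0.000241), or 2.53-fold. With the arrays of each line averaged first, 2 means against 2, the adjusted p for ZFX was 0.07. In the authors' processed values the log2 fold was 0.702.

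Under the background correction used, the named genes with the largest rises in the ZFX lines were NPTX1, SEPTIN5 and CLC. This order depended on the correction. In the authors' processed values WDR72 (1.53), RAB17 (1.26) and SEPTIN5 (1.26) led the 12 rises. Without correction WDR72 (1.67), SEPTIN5 (1.52) and SYT4 (1.35) did. NPTX1, a neuronal pentraxin of synapses, rose by 2.19 on the log2 scale (SE 0.16) and was detected on 1 of the 4 control arrays. SYT4, a synaptotagmin, rose by 1.83 (SE 0.138), and SEPTIN5, a septin, by 2.13 (SE 0.134). A second SEPTIN5 probe had a log2 fold of 0.21 that did not pass. CLC, the Charcot-Leyden crystal galectin, rose by 2.04, WDR72 by 1.96, the Groucho-type corepressor TLE2 by 1.62 and the potassium channel KCNJ2 by 1.52. RIPOR2 rose by 1.48, the zinc finger gene TSHZ3 by 1.44, the diacylglycerol kinase DGKK by 1.43 and the small GTPase RAB17 by 1.38. BEX5 was not detected in the control lines and was at least 2.39-fold higher in the ZFX lines under the background correction used, with an adjusted p of 2.09e-05. Folds of dim genes depended on that correction: without it the log2 fold was 1.11 for NPTX1, 0.72 for BEX5, 1.06 for CLC and 0.71 for KCNJ2, and in the authors' processed values 0.80, 0.49, 0.77 and 0.49. The control means of NPTX1 (4.64) and KCNJ2 (4.67) lay below the dimmest detected probe of each array (4.76 to 4.82). The size of their rises is therefore uncertain. Of the 48 genes named for this comparison, 26 had folds over 1.5 times smaller in the authors' values, and 0 changed sign. Several of these genes also differed between the controls. In clone 3 against H9, RIPOR2 was lower by -1.51 on the log2 scale, TLE2 by -1.08 and TSHZ3 by -0.70. DGKK rose by 1.94 in clone 2 and 2.41 in clone 5 against clone 3, and by 0.44 and 0.91 against H9. Against H9, RIPOR2 rose by 0.57 and 0.88 in these clones, TLE2 by 1.17 and 1.01, and TSHZ3 by 1.15 and 1.03. Another DGKK probe had a log2 fold of 0.31 that did not pass. DGKK lost its call without clone 2 replicate 2 or either clone 5 array (adjusted p 0.0527 to 0.0626).

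**Figure D1:**
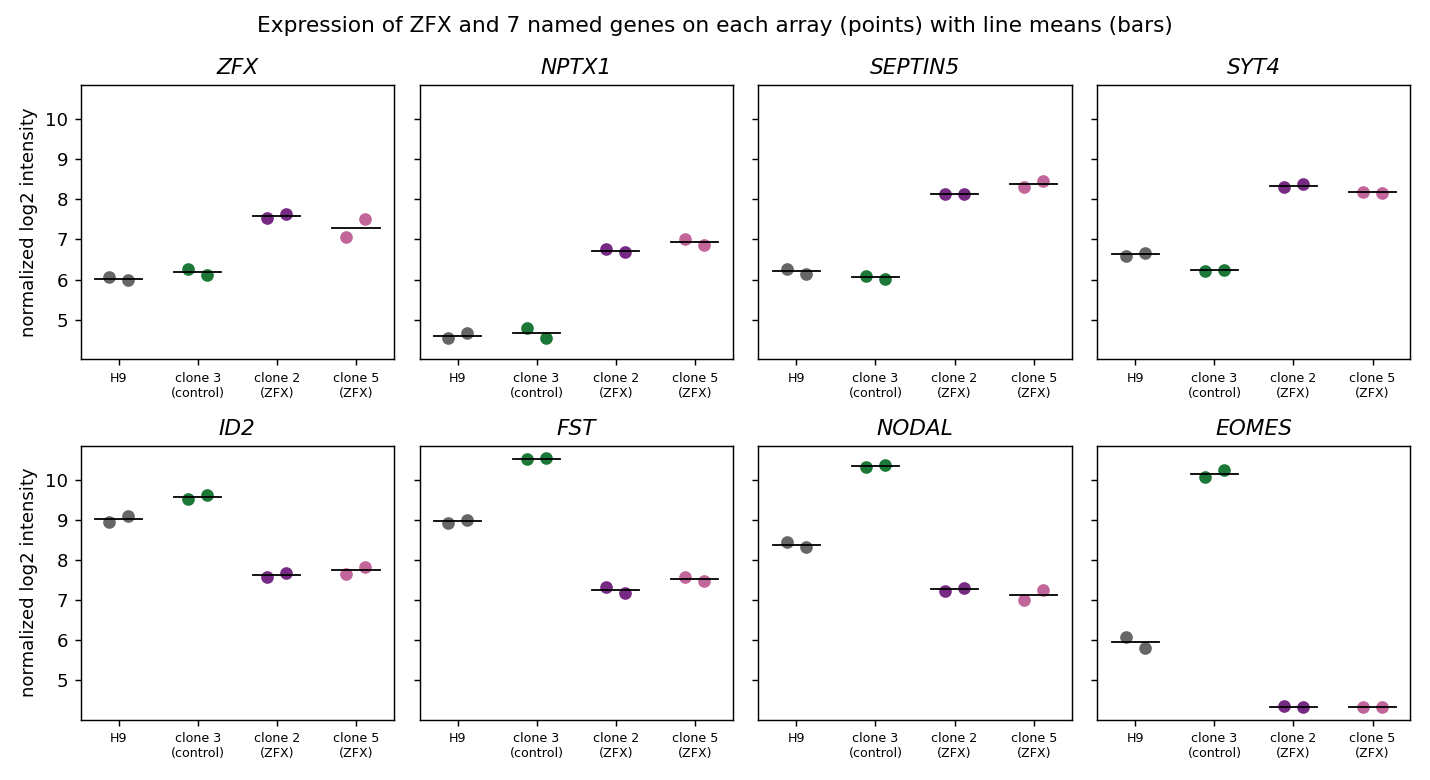
Normalized log2 intensity (vertical axis) of ZFX and 7 named genes on each array (points), grouped by line (horizontal axis), with line means as bars. ZFX has line means of 6.02 and 6.19 in the controls and 7.60 and 7.30 in the ZFX lines, while EOMES and NODAL also differ between the 2 control lines.

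Genes of mesendoderm and of Nodal and Wnt signalling were among those with the largest falls. EOMES, a T-box factor of early mesendoderm, was not detected in the ZFX lines and was at least 9.57-fold lower there under the background correction used, with an adjusted p of 0.0108. The signalling ligand NODAL fell by 2.17 on the log2 scale (SE 0.35), the activin-binding protein FST by 2.35 (SE 0.289) and the Wnt-responsive factor SP5 by 2.24 (SE 0.525). SP5 was detected on 0 arrays of clone 2 and 1 of clone 5. Its mean in the ZFX lines, 4.75, lay below the dimmest detected probes (4.76 to 4.82), so the size of its fall is uncertain. GLIPR1L1 fell by 3.61, ECHDC3 by 1.99, LRFN5 by 1.99, the retinoic acid hydroxylase CYP26A1 by 1.95, the hyaluronan synthase HAS2 by 1.88 and the transporter SLC47A1 by 1.85. GAD1, a glutamate decarboxylase, was at least 5.25-fold lower and WLS, a carrier of Wnt proteins, at least 3.20-fold lower. The other 3 WLS probes had log2 folds of -0.55, -0.55 and -0.48 that did not pass, and neither did the other 2 GAD1 probes (-1.84 and -1.85), 1 CYP26A1 probe (-1.41) and 1 HAS2 probe (0.08). In the authors' processed values the log2 fold was -2.01 for EOMES, -1.33 for GAD1, -0.71 for WLS and -1.04 for SP5, smaller than the folds and bounds above. SP5, CYP26A1, GAD1, LRFN5 and WLS each lost their call without any 1 array of clone 2, clone 5 or clone 3 (adjusted p 0.0555 to 0.102). All 12 of these genes were also higher in clone 3 than in H9, from 0.49 on the log2 scale for ECHDC3 to 2.97 for SP5, 3.51 for GAD1 and 4.20 for EOMES. Their SEs and adjusted p-values understate this difference between the controls. None of the 12 passed when the arrays of each line were averaged first. Against H9 the log2 fold in clones 2 and 5 was -2.08 and -2.58 for GLIPR1L1, -2.33 and -1.16 for ECHDC3, -1.71 and -1.43 for FST, and -1.40 and -1.07 for HAS2. It was -1.12 and -1.26 for NODAL, -0.81 and -0.94 for SLC47A1, and -0.91 and -0.48 for CYP26A1. Where a clone had no detected signal only a bound was left: EOMES was at least 2.24-fold and 2.23-fold lower than in H9, GAD1 at least 1.56-fold and 1.55-fold, and WLS at least 1.48-fold in both clones. SP5 was at least 1.64-fold lower in clone 2 and had a log2 fold of -0.63 in clone 5, and LRFN5 had -0.52 in clone 2 and was at least 1.75-fold lower in clone 5.

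In all, 321 of 19124 genes passed the test between ZFX and control lines, 214 higher and 107 lower in the ZFX lines, and 52 and 42 of them by at least 2-fold. All 321 had the same sign in the 4 pairs of a ZFX and a control line. With median scaling in place of quantile normalization 477 passed, 260 higher and 217 lower, so the share of higher genes was 54.5% against 66.7%. The count was 1095 with H9 as the only control and 2594 with clone 3 alone, 12 when line means were compared, 2876 with line fixed, 565 with line ignored, 191 without an intensity trend, 131 and 41 with clone 2 or clone 5 as the only ZFX line, and 178, 176 and 201 without clone 2 replicate 1, clone 2 replicate 2 or clone 5 replicate 1.

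Of the 34 gene lists, 8 passed in this comparison, 2 up and 6 down, and all 8 passed with an estimated correlation. Another pairing of the 4 lines, H9 and clone 5 against clone 3 and clone 2, gave 12 lists. H9 and clone 2 against clone 3 and clone 5 gave 7, and splits that break lines up gave up to 6. Lists therefore also passed in groupings that mix ZFX and control lines. Between ZFX and control lines, 5 passed without clone 3 replicate 1. Against H9 alone 4 passed, 2 of these also with an estimated correlation, and against clone 3 alone 10. The primitive streak list had the lowest median, -1.51 over 9 tested genes (adjusted p = 1.88e-07). EOMES was its only member to pass over all genes, and 7 members were lower when adjusted over the list alone. Against clone 3 alone the median was -2.70, and against H9 alone -0.0608 (adjusted p = 0.00251, and adjusted p = 0.0551 with an estimated correlation), both alternatives chosen after seeing the data. The list of targets of bone morphogenetic protein signalling passed as lower against both controls, with a median log2 fold of -0.234 between ZFX and control lines. In that list of 8 tested genes, ID2 fell by 1.62 and ID1 by 0.56 on the log2 scale (list adjusted p = 4.36e-07), and 3 members were lower when adjusted over the list alone. Over all genes 6 members did not pass. In clone 2 against H9, 4 members were lower and 1 was higher. Against H9 alone the adjusted p of the list was 3.3e-05, and against clone 3 alone 2.42e-05.

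The Wnt target list (11 tested, median -0.316, adjusted p = 0.00032) and the Nodal and activin list (9 tested, median -0.228, adjusted p = 0.00143) each had 1 member that passed over all genes, SP5 and NODAL. Adjusted over the list alone, 4 and 1 members were lower. Neither list passed against H9 alone. The endoderm list (12 tested, median -0.105, adjusted p = 0.0363), the cell cycle list (39 tested, median -0.0865, adjusted p = 0.0363) and the cholesterol synthesis list (18 tested, median 0.163, adjusted p = 0.00762) had 0 members that passed, over all genes or adjusted over the list alone. The member with the largest log2 fold in size was FOXA2 at -1.73 for endoderm, CDC6 at -0.36 for cell cycle and IDI1 at 0.29 for cholesterol synthesis. The cell cycle list did not pass without H9 replicate 1, either clone 2 array or clone 3 replicate 1 (adjusted p 0.0563 to 0.112), endoderm without clone 2 replicate 2, either clone 3 array or clone 5 replicate 2 (0.0563 to 0.16), and cholesterol synthesis without clone 3 replicate 1 (0.0514). The cholesterol synthesis list also did not pass under median scaling (adjusted p = 0.221, mean log2 fold 0.0666 against 0.146) or against H9 alone (0.656), nor did endoderm against H9 alone (0.676), or cell cycle against H9 alone (0.241) or clone 3 alone (0.114, and adjusted p = 0.0495 with an estimated correlation).

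The list of genes around ZFX on the X chromosome passed with a median log2 fold of only 0.0443 (10 tested, mean 0.292, adjusted p = 1.86e-05). In that list 3 members rose and 7 did not pass, and 4 were higher when adjusted over the list alone. Besides ZFX, ACOT9, an acyl-CoA thioesterase, rose by 0.80 on the log2 scale (SE 0.146) and PRDX4, a peroxiredoxin, by 0.49 (SE 0.0878). Another ACOT9 probe had a log2 fold of 0.63 that did not pass. Of 6 protein-coding genes lying between ACOT9 and ZFX, 4 were tested, with log2 folds of 0.01 for SAT1, 0.03 for APOO, 0.05 for KLHL15 and 0.04 for EIF2S3 that did not pass. Without ZFX itself, an alternative chosen after seeing the data, the list had a median of 0.0368 and an adjusted p of 0.00762 by limma's cameraPR.

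Core pluripotency genes had small folds that did not pass. The log2 fold was -0.16 (SE 0.106) for POU5F1, -0.24 (SE 0.135) for NANOG and -0.01 (SE 0.124) for SOX2. Of 34 tested genes of the pluripotency list, 2 rose, DPPA2 by 0.96 and UTF1 by 1.38, and 3 were higher when adjusted over the list alone (list adjusted p = 0.808, with a median of -0.013 although the test pointed up). UTF1 was not detected in clone 3. Against H9 its log2 fold was 0.63 in clone 2 and 0.40 in clone 5, where it did not pass (adjusted p = 0.138), and in the authors' processed values the fold over both controls was 0.52 for UTF1 and 0.50 for DPPA2. UTF1 lost its call without any 1 array of clone 2, clone 5 or clone 3 (adjusted p 0.0901 to 0.122). Neuroectoderm genes went both ways, with 3 of 14 higher and 2 lower. TUBB3, a neuronal tubulin, rose by 0.61, HES5 by 0.63 and POU3F1 by 0.90, while OTX2 fell by 1.23 and FABP7 by 0.69 (list adjusted p = 0.66). Another POU3F1 probe had a log2 fold of 0.11 and another OTX2 probe -0.78, and neither passed. Adjusted over the list alone, 4 were higher and 4 lower. Of 24 mesenchymal genes, the intermediate filament gene VIM fell by 1.21 and TAGLN by 1.14, and the list did not pass (adjusted p = 0.432, with a median of 0.0278 although the test pointed down). The same 2 were lower when adjusted over the list alone. With an array left out, POU3F1, HES5 and FABP7 lost their call in 6, 6 and 4 of 8 fits, and TAGLN without either clone 5 array (adjusted p 0.0553 and 0.0597). Of the 26 lists that did not pass, the lowest adjusted p was 0.132, for mesoderm, where ACTC1 fell by 1.03.

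Pairs of single lines differed in more genes, as their p-values measure the spread within lines. Clone 2 differed from H9 in 2905 genes (1655 higher) and from clone 3 in 3106 (1698 higher). Clone 5 differed from H9 in 1060 genes (600 higher) and from clone 3 in 3273 (1701 higher). Leaving out an array of the lines compared, other than H9 replicate 1, gave 1670 to 1860 for clone 2 against H9, 1925 to 2177 for clone 2 against clone 3, 602 to 636 for clone 5 against H9 and 2078 to 2451 for clone 5 against clone 3. Under median scaling the clone 2 counts were 558, 46.4% higher against 57.0%, and 1318, 41.4% higher against 54.7%, and the clone 5 counts 205 and 1286. Without an intensity trend the 4 counts were 1434, 2029, 277 and 2083. A set of 343 genes passed with the same sign in all 4 pairs of a ZFX and a control line, 226 higher and 117 lower, and 267 of these were among the 321. The same count was 138 (64 higher and 74 lower) for H9 and clone 5 against clone 3 and clone 2, a pairing that mixes ZFX and control lines, and 17 for H9 and clone 2 against clone 3 and clone 5. In 20 simulations without any change, 0 to 4 genes did so. Those simulations drew line effects from 1 correlation for all genes, so the 138 and 17 of the real pairings are the closer comparison. Under median scaling the set held 85 genes, 45 higher and 40 lower, or 52.9% higher against 65.9%. Without clone 5 replicate 1 it held 223.

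Line pairs that share no array were compared gene by gene, with genes not being independent replicates. Log2 folds of clone 2 over clone 3 and of clone 5 over H9 correlated across genes at r = 0.306 (rho 0.177), and those of clone 2 over H9 and of clone 5 over clone 3 at r = 0.102 (rho -0.0258). In the first pair 287 genes were called higher in both, against 53.3 for independent lists, 169 lower in both against 33.9, and 63 opposite against 85. In the second pair 388 were higher in both against 147, 193 lower in both against 103, and 457 opposite against 247. The remaining pair, clone 3 over H9 and clone 5 over clone 2, has no ZFX contrast in common and gave r = -0.206 (rho -0.213). There 20 genes were called higher in both against 20.2, 41 lower in both against 41.6, and 242 opposite against 61.7, so counts above those of independent lists also arose without a ZFX contrast.

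**Figure D2:**
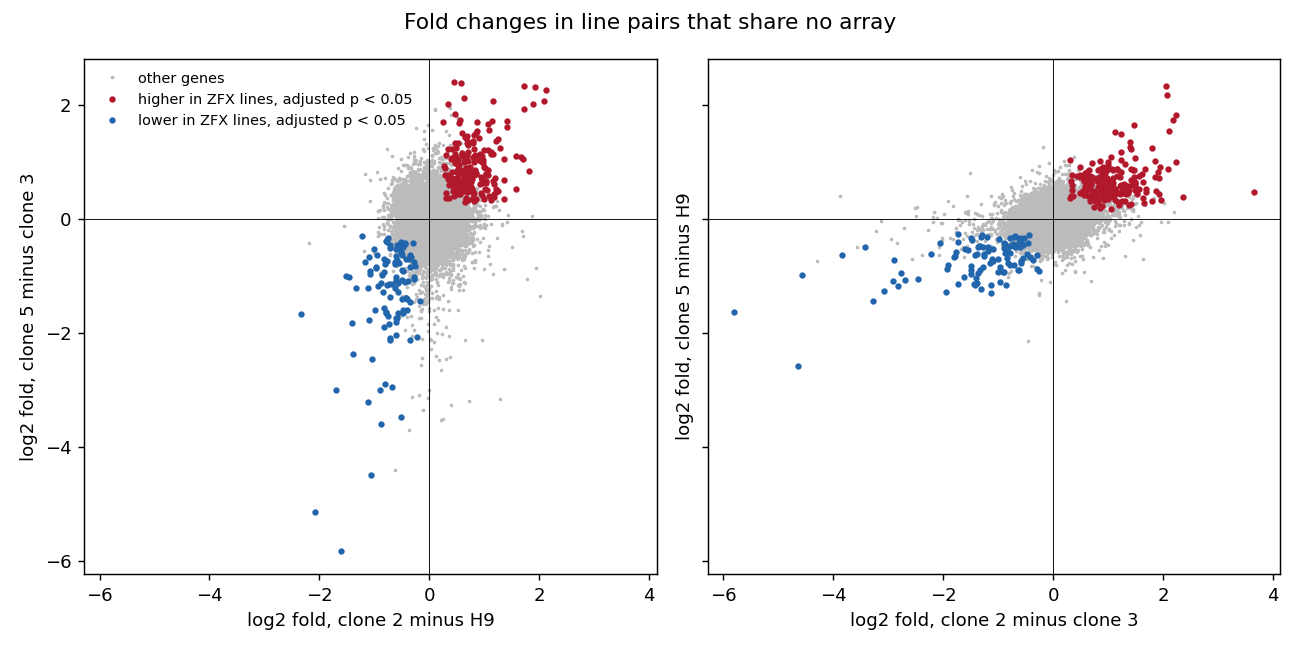
Log2 fold changes of each gene (points) in 2 line pairs that share no array, clone 2 minus H9 against clone 5 minus clone 3 (left) and clone 2 minus clone 3 against clone 5 minus H9 (right). Red and blue points are the 214 higher and 107 lower genes of the ZFX lines, grey points all other genes, and the correlation over all genes is 0.102 on the left and 0.306 on the right.

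The 2 control lines, neither labelled as a ZFX line, differed in primitive streak genes, among others. In clone 3 EOMES was higher than in H9 by 4.20 on the log2 scale, the endoderm factor FOXA2 by 3.76, MIXL1 by 3.67, GAD1 by 3.51, ARRB1 by 3.26, FGF8 by 3.21 and CER1, a Nodal antagonist, by 3.17. TBXT, the mesoderm factor brachyury, was not detected in H9 and was at least 6.23-fold higher in clone 3. SFRP1 was lower by -2.02, BTBD17 by -1.99, TTYH1 by -1.82, CCN1 by -1.61, PCDHB5 by -1.58, JPH4 by -1.57 and RIPOR2 by -1.51. UTF1 was not detected in clone 3 and was at least 2.7-fold lower. The other 3 ARRB1 probes had log2 folds of 1.80, 1.79 and 0.21, the last of which did not pass. In the authors' processed values 11 of the 16 genes named for clone 3 against H9 had folds over 1.5 times smaller. There the log2 fold was 2.97 for EOMES, 2.01 for MIXL1, 1.63 for FGF8, 1.28 for TBXT, -0.89 for TTYH1, -0.56 for UTF1 and -0.52 for JPH4. In all, 3778 genes passed, 1883 higher and 1895 lower in clone 3. The count was 1208 under median scaling, 666 higher and 542 lower, 2302 without an intensity trend, and 2401, 2414 and 2361 without H9 replicate 2, clone 3 replicate 1 or clone 3 replicate 2.

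Of 9 tested primitive streak genes 7 were higher in clone 3, also when adjusted over the list alone, with a median of 2.38 (list adjusted p = 4.65e-52). The Nodal and activin list had 5 of 9 members higher and 1 lower, and 6 and 1 adjusted over the list alone. LEFTY2 rose by 2.53, GDF3 by 2.50 and NODAL by 1.95. All 7 tested metallothioneins, metal-binding proteins, were lower in clone 3, also when adjusted over the list alone (median -0.603, adjusted p = 1.16e-08). MT1M had a log2 fold of -0.79 and MT2A of -0.65. Another MT1E probe had -0.17 and another MT1H probe 0.08, and neither passed. Pluripotency genes were lower on balance, 16 lower and 4 higher of 34 (median -0.25, adjusted p = 0.00808), and 18 and 5 adjusted over the list alone. POU5F1 had a log2 fold of -0.27, with another probe at -0.01 that did not pass, and NANOG, which was higher, of 0.47. Of 18 cholesterol synthesis genes 8 were lower and 2 higher (adjusted p = 0.0114), and 9 and 2 adjusted over the list alone. Among Wnt targets 5 of 11 were higher, with AXIN2 at 1.06 and DKK1 at 1.03 (6 adjusted over the list alone, list adjusted p = 3.14e-11). Hypoxia and glycolysis genes had 7 of 22 higher and 2 lower, with BNIP3 at 1.85 (8 and 2 adjusted over the list alone, list adjusted p = 0.00749). In all, 13 lists passed, and 11 of these also with an estimated correlation.

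**Figure D3:**
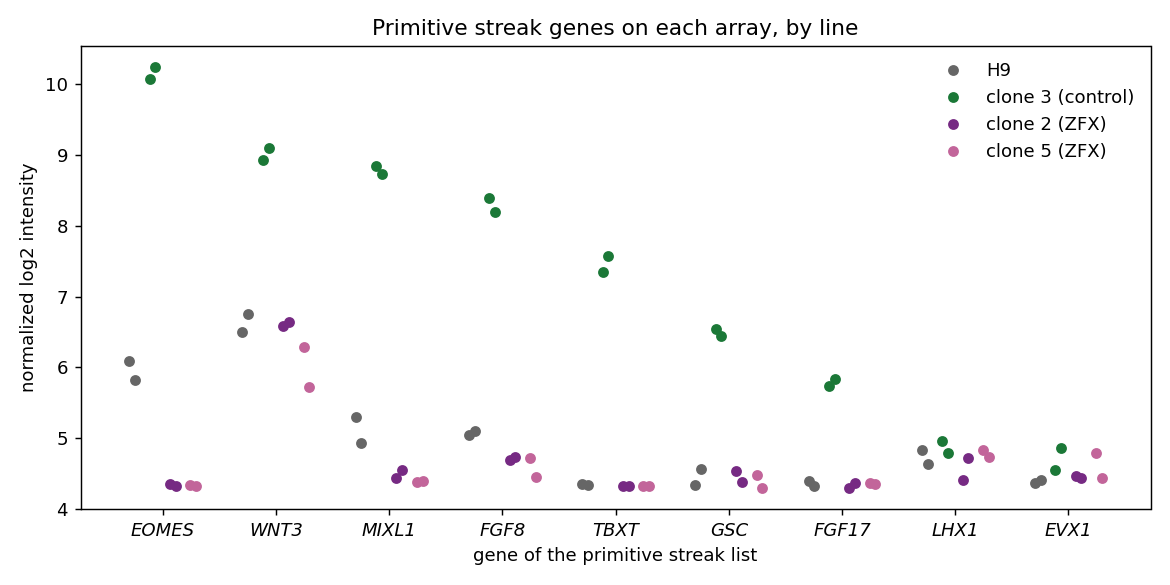
Normalized log2 intensity (vertical axis) of the 9 tested primitive streak genes (horizontal axis) on each array, with the line shown by colour. Both clone 3 arrays lie above all other arrays for 7 genes, from EOMES, with a clone 3 mean of 10.15, to FGF17, with 5.79.

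The 2 ZFX lines differed from each other in 625 genes, 205 higher and 420 lower in clone 5 than in clone 2. ECHDC3 was higher in clone 5 by 1.17 on the log2 scale, OTX2, a forebrain homeobox factor, by 1.05, LRRC58 by 0.88, KLC2 by 0.81, NPDC1 by 0.79, SFRP1 by 0.78, EPB41 by 0.77 and CUZD1 by 0.76. KIAA0040 was lower by -1.92, LCP1 by -1.32, NUAK2 by -1.21, RPL10L by -1.19, TSPAN18 by -1.18, ARRB1 by -1.18 and ANXA1 by -1.14. TSPYL5 was not detected in clone 5 and was at least 2.44-fold lower under the background correction used. In the authors' processed values 15 of the 16 genes named for clone 5 against clone 2 had folds over 1.5 times smaller, among them 0.23 for KLC2, 0.23 for NPDC1, -0.49 for TSPYL5, -0.40 for RPL10L and -0.39 for ANXA1. The KIAA0040 fold came from 1 array, as its log2 intensity in clone 2 was 5.35 on replicate 1 and 8.88 on replicate 2. Without clone 2 replicate 2 the log2 fold was -0.15 for KIAA0040, 0.36 for EPB41 and 0.30 for NPDC1, none of which passed (adjusted p 0.828, 0.42 and 0.599), and without clone 2 replicate 1 it was -3.68, 1.18 and 1.27. Other probes that did not pass had log2 folds of 0.15 for OTX2, 0.18 for KLC2, -0.14 for EPB41, -0.31 for NUAK2 and 0.06 for ARRB1. Of 16 tested immediate early genes 5 were lower in clone 5, among them ATF3 at -0.75 and JUN at -0.73, and 9 adjusted over the list alone (list adjusted p = 3.81e-09). Of 7 metallothioneins 3 were higher, MT1M by 0.65, MT2A by 0.42 and MT1E by 0.31 (another MT1E probe had -0.17 and did not pass), and 4 adjusted over the list alone (list adjusted p = 0.000199). In all, 9 lists passed, and 7 of these also with an estimated correlation. Under median scaling 48 genes passed, 20 higher and 28 lower, or 41.7% higher against 32.8%. Without an intensity trend in the variance 48 passed. Leaving out clone 2 replicate 1 or 2, or clone 5 replicate 1 or 2, gave 183, 244, 293 and 315 genes. KLC2, NPDC1, EPB41, CUZD1 and KIAA0040 lost their call in 2 or 3 of these fits.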

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

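The tests of pairings of whole lines, of mislabelling, of cell mixtures and of the ZFX neighbourhood were chosen after the results were seen. The 35 splits were planned before they were counted, except that the real split and the 2 other pairings of whole lines had been counted earlier.

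The effects of the 2 ZFX clones against the same controls differed in 625 genes. Among genes named for the ZFX lines, the log2 fold of clone 5 minus clone 2 was 1.17 for ECHDC3, 1.05 for OTX2, -0.931 for TAGLN, -0.585 for DPPA2, -0.498 for GLIPR1L1 and 0.468 for DGKK. It was -0.451 for ACOT9, 0.428 for CYP26A1, -0.385 for ACTC1, -0.32 for RAB17 and 0.31 for RIPOR2. For all of these the test of the difference itself passed. Other probes, which did not pass, gave 0.15 for OTX2, -0.35 for TAGLN, -0.12 for DGKK, and -0.21 and 0.03 for CYP26A1.

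The 321 genes that differ between ZFX and control lines were set against other groupings: of the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, gave as many genes, and the highest other split gave 36. This lead was not seen before adjustment. At an unadjusted limma p under 0.05 the real split gave 1974 genes. The split of H9 and clone 5 against clone 3 and clone 2 gave 2226. For the 8 gene lists 2 splits gave as many, with 12 in the highest other. The 32 splits that break lines up called 0 genes each and up to 6 lists. They say nothing about how whole lines were grouped, and the 3 that keep lines whole are too few for a share under 0.05. Of those 3, H9 and clone 2 against clone 3 and clone 5 called 0 genes but 7 lists. Clonal differences unrelated to ZFX cannot be told apart from an effect of ZFX, and H9 and clone 5 against clone 3 and clone 2 gave those 36. A part of array brightness in these calls was not settled. Between the brighter and dimmer array of a line, called genes moved by a median of -0.000743 log2 in the direction of their fold, against a median fold of 0.815. Genes that vary between the arrays of a line are less often called, so a small value was favoured in advance. Brightness differences between lines were not tested.

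The primitive streak genes were high in clone 3, a wild-type clone for which the labels do not say whether it was drug selected. A single mislabelled array is argued against, since the list means of the 2 clone 3 arrays differed by 0.0429 log2 and lay 2.23 above the nearest other array. Fibroblast-like cells mixed into the culture stay open, since the mesenchymal list went both ways: of its 14 members that passed, 8 (57.1%) were higher in clone 3 than in H9, among them COL6A2 by 1.37, TAGLN by 0.92 and VIM by 0.61, and 6 lower, among them COL1A1 at -1.41 and COL1A2 at -0.44 (another probe had -0.15). A loss of undifferentiated cells to all lineages alike is argued against, as the highest median of the neuroectoderm, trophoblast and mesenchymal lists was 0.0759 against 2.38. Differentiation toward mesendoderm in that culture, drug selection or a lasting property of the clone may account for the pattern, and none of these was tested.

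ACOT9 and PRDX4 rose with ZFX, which lies near them. Whole neighbouring genes on the BAC or on a duplicated segment from ACOT9 to ZFX are argued against. The 4 tested of 6 protein-coding genes in between had a mean log2 fold of 0.0323, with an upper 95% limit of 0.159. That limit treats the 4 genes as independent, though they were measured in the same lines. A shift of the whole X chromosome is argued against by its median log2 fold of -0.00204 over 492 genes. Of these 492 genes, 17 rose and 7 fell, while 195 of all 12579 genes with a chromosome rose. The median does not speak to an excess of rises among single X-linked genes, which was not tested. A response of ACOT9 and PRDX4 to the ZFX protein stays open as a biological explanation and was not tested.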

How the results depend on the processing

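With arrays of a line averaged first, the ZFX fold stayed at 1.34 with an adjusted p of 0.07; over all other alternatives it passed, from 0.702 with the authors' values to 1.49 with clone 2 as the only ZFX line, and from 1.28 to 1.46 with an array left out. The 321 genes became 213 under the stricter filter, 2876 with line fixed, 12 with line means, 565 with line ignored, 2594 against clone 3 alone, 1095 against H9 alone, 131 with clone 2 and 41 with clone 5 as the only ZFX line, and 191 without the intensity trend. Fewer lines or tests enter in several of these, and otherwise the cause was not tested. Under median scaling, clone 2 against H9 gave 558 genes, clone 2 against clone 3 1318, clone 3 against H9 1208, clone 5 against H9 205, clone 5 against clone 2 48, clone 5 against clone 3 1286, and all 4 pairs together 85. Without the trend these were 1434, 2029, 2302, 277, 48, 2083 and 138. With no filter, clone 5 against clone 2 gave 414. The correlation of clone 2 over clone 3 with clone 5 over H9, 0.306 (jackknife SE 0.0438), was 0.259 with no filter, 0.361 with the stricter filter and 0.381 in the upper expression range. The 8 lists became 13 with fry, which does not compare a list with other genes, and 4 against H9 alone, where the lists of chromosome segment 20q11 and of primitive streak genes were lost with an estimated correlation (adjusted p = 0.0851 and 0.0551), against 10 for clone 3 alone, alternatives added after seeing the data.

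With an array left out, the ranges were 176 to 445 for ZFX against control lines, 1670 to 2995 for clone 2 against H9, 1925 to 3326 for clone 2 against clone 3, 2361 to 3843 for clone 3 against H9, 602 to 991 for clone 5 against H9, 183 to 758 for clone 5 against clone 2, 2078 to 3470 for clone 5 against clone 3, 223 to 277 for all 4 pairs, 5 to 10 for lists, and 0.0734 to 0.119 and 0.253 to 0.303 for the correlations. The normalization of all 8 arrays was kept, and a lone array of a line was assumed to vary like the others. The cell cycle and endoderm lists lost their call in 4 of these fits each and cholesterol synthesis in 1. Cholesterol synthesis was also lost under median scaling (adjusted p = 0.221), cell cycle with the stricter filter (0.0824), line fixed (0.0555), line means (0.0757) and no trend (0.0777), and endoderm with line means (0.0757), line ignored (0.077) and no trend (0.0549). Of 1200 refits of the 48 genes named for the ZFX lines, 960 kept direction and call, 240 kept direction only and 0 reversed. The 48 were named for passing, and all 321 called genes had the same sign in the 4 line pairs. Fits that drop, average or ignore lines therefore could not reverse them. All 286 refits for clone 3 against H9 kept both, and 261 of 288 for clone 5 against clone 2. These genes were also named for passing with the largest folds, so keeping their call was favoured in advance. TBXT, detected only on the 2 clone 3 arrays, was not tested when 1 of these was left out. Such fits are not among the 286. Replicate numbers did not pair the samples (correlations of deviations -0.00991 to 0.0628). With the replicate block 218 genes passed between ZFX and control lines. A block for the slide was not run, since the files name none. Signal over background of 12.3 to 15.7 limits what dim genes can show.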

Other observations

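The families described here were chosen after their values were seen, and the tests of whole chromosomes and of the BEX and TCEAL genes after the result was seen. Members said to rise kept their sign under median scaling, without background correction and in the authors' values, where the folds were smaller. Among 13 tested synaptotagmins, vesicle proteins, 3 rose in the ZFX lines and 0 fell: SYT4 by 1.83 on the log2 scale, SYT11 by 1.33 and SYT9 by 0.74. Of 9 tested HLA class II genes 2 rose, HLA-DRA by 1.27 and HLA-DMB by 1.16. CD74, their invariant chain, had a log2 fold of 0.35 and HLA-DPA1 of 0.20, and neither passed. The acyl-CoA thioesterases ACOT1 and ACOT2 rose by 1.14 and 1.11. They are close paralogs, so which of them a probe measured is uncertain. Low values in clone 3 make up part of some of these folds. In H9, clone 3, clone 2 and clone 5, ACOT2 had mean log2 intensities of 5.84, 4.688, 6.381 and 6.371. For ACOT1 these means were 5.016, 4.412, 5.823 and 5.893, and for SYT9 5.016, 4.495, 5.454 and 5.546. In the authors' values the log2 fold was 0.35 for ACOT1, 0.39 for ACOT2, 0.38 for HLA-DMB, 0.72 for HLA-DRA, 0.22 for SYT9 and 1.13 for SYT4.

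BEX and TCEAL genes lie together on the X chromosome, and 4 of the 12 tested rose: BEX5, BEX1 by 0.60, TCEAL3 by 0.63 and TCEAL7 by 0.52 (0.31 in the authors' values). Another BEX1 probe had a log2 fold of 0.36 that did not pass. A rise of the whole cluster was the hypothesis. The median log2 fold over the 12 genes was 0.152, with an upper 95% limit of 0.247, below the 0.3 that a shared rise was set to need, which argues against a rise of all members alike. This limit treats the genes as independent, though they were measured in the same lines. It also leaves out the spread between them, from -0.12 for TCEAL9 to 1.57 for BEX5. Gain or loss of a whole chromosome in a line was tested over 23 chromosomes and 6 line pairs. The largest median log2 fold in size was 0.0768, for chromosome 20, and the lowest adjusted p of the 138 tests was 0.428, which argues against such a gain or loss in most cells of a line.

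When the arrays of each line were averaged, 12 genes passed, 10 higher and 2 lower in the ZFX lines. The higher ones were NPTX1, SEPTIN5, CLC, WDR72, SYT4, BEX5, KCNJ2, RAB17, SYT11 and BBS9, and the lower ones SOCS2, with a log2 fold of -1.27, and ID2, with -1.62. None of the primitive streak genes was among them. SOCS2, BBS9 and SYT11 were named after their values were seen.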
